A study of Mus musculus with 5 samples.

How the data were processed

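The data were RNA-seq counts per gene from 5 libraries of cells from the mouse colon lamina propria, 2 of Treg cells and 3 of Foxp3 reporter-null cells. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, cells were lysed in TRIzol, polyadenylated RNA was amplified with the SMART-Seq v4 kit, libraries were made with the KAPA Hyper Prep kit, and paired-end reads were sequenced on an Illumina HiSeq. The values are whole-number counts per gene symbol that the authors deposited as a single table, with no normalisation, per the file headers and the values. DESeq is named in the submitters' processing notes with no version or role. The aligner, genome build, annotation, strand setting and treatment of reads that match several genes are not given in the sources used here, so no coordinates are printed, and reads of overlapping, antisense or near-identical genes cannot be told apart. Amplified reads carried no molecular identifiers, so each count is a read count and not a count of molecules.

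Of the 24421 rows of the table, 4 carried the name NA and were left out of library sizes and tests. They held 0.0034% to 0.00492% of the counts of a library. No column was left unused. The total count per library ran from 17670420 to 22395169, and the 10 most abundant genes took 4.38% to 7.55% of it. Replicates were compared by a chi-square of their counts per gene, and no pair agreed within sampling noise (22.3 to 97.3 per degree of freedom).

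Counts were analysed in R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 14164 genes. Library sizes were scaled with TMM factors, and groups were compared with the quasi-likelihood F test of edgeR 4.0.16 in its robust form, with Benjamini-Hochberg adjustment and a threshold of 0.05. The standard error of a log2 fold change was its size divided by the square root of F. The common biological coefficient of variation was 0.401, and the median log2 fold change of the tested genes was 0.018. Principal components were computed from log2 CPM with a prior count of 2.

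A total of 38 gene lists were written, 25 for programmes of CD4 T cells, 3 for RNA quality and dissociation and 10 for markers of other cell types. Of these, 37 had tested members. They were compared with the other genes by camera of limma 3.58.1, two-sided, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the lists. Of the 37 lists 21 passed, 8 towards higher and 13 towards lower values in reporter-null cells. With a correlation estimated from the data 1 passed, the Treg signature. Some lists lost their call although their estimate was below the preset, such as -0.032 for suppressive mediators and -0.03 for homing receptors. In others it was above, such as 0.339 for T cell cytokines. With the preset, camera takes its degrees of freedom from the number of genes, and with an estimate from the few libraries. The lost calls therefore do not by themselves show correlation between the genes of a list. Members of a list were also adjusted over the list alone. Lists share genes, so their tests are not independent.

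The rule for named genes had several parts. Foxp3 and Thy1 came first. A fixed set of genes was always named, from Il2ra to Il4. In each direction the 8 largest fold changes were named among genes past the threshold, with an average log2 CPM of at least 3 and no overlap between the groups, leaving out gene models without a curated symbol, immunoglobulin and T cell receptor variable segments and mitochondrial genes. Up to 4 members with the smallest p were named per list. Some genes that the rule names are not reported here. Further list members named in the text as called or as not called are there to describe a list's count. The groups, lists, tests, rule and alternatives, with the exception named below, were fixed before the data were examined. For a gene with no count in a group, the limit was 3 counts over the group, and for a gene with 1 to 3 counts the ratio has a 95% counting interval.

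The steps were tested on simulated counts for this comparison, drawn for the 14164 genes with 50 genes planted at each fold size. With edgeR 40% of the genes planted at a log2 fold change of 1 were recovered, 70% at 2, 64% at 3 and 80% at 4, and 13 calls (9.3%) were false. DESeq2 recovered 42%, 78%, 70% and 92% with 28.4% of its calls false, and limma-voom 36%, 68%, 46% and 74% with 14.5% false. In a separate draw only the glycolysis genes were shifted, by 1.5 on the log2 scale. That list was found, and 0 of the other lists were called. Genes were drawn independently of each other, so this draw does not test the list calls where genes vary together.

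Alternatives were RLE and upper quartile factors, DESeq2 1.42.0, limma-voom with and without sample quality weights, no filter, a filter on a CPM of 1 in at least 2 libraries, counts thinned to the shallowest library, stricter thresholds, each library left out in turn, and replicate blocks by the number in the titles and by the number in the descriptions. For the lists they were the estimated correlation, the rotation test fry, which tests whether a list moves one way on balance and not against other genes, both other scalings, no filter, the left-out libraries and the blocks. Leaving out Treg replicate 1 and reporter-null replicate 2 together was added after the data were seen. Ranges of adjusted p given beside a single alternative cover the alternatives other than the blocks, and for lists also other than the estimated correlation and fry. Where a fit had a single Treg library, that library was assumed to vary like the reporter-null libraries. The fit without both Treg replicate 1 and reporter-null replicate 2 is of this kind and sets the low end of some ranges. A very small adjusted p from such a fit is no measure of strength. Neighbours of Foxp3 were taken from the gene order of the RefSeq annotation of GRCm38.p6, used for names and order only.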

Results

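RNA was sequenced from cells of the mouse colon lamina propria, the connective tissue layer beneath the gut epithelium. The mice carried a Foxp3 allele marked with DTR-GFP together with a Foxp3 reporter-null allele, in which a Thy1.1 reporter and a stop signal between loxP sites precede GFP. Foxp3 is the transcription factor that defines regulatory T (Treg) cells. The Treg group held 2 libraries of cells positive for Foxp3-DTR-GFP, and the reporter-null group held 3 libraries of Thy1.1-positive cells. The total counts were 17670420 and 22245610 in Treg replicates 1 and 2, and 19011118, 20650154 and 22395169 in reporter-null replicates 1, 2 and 3. The labels do not say that the libraries came from separate animals, so the p-values of single genes measure the spread between these libraries, which may be technical. Set tests with the preset correlation judge a list against the spread between genes. Their very small p-values are therefore no measure of the spread between libraries. Reporter-null replicate 1 joins the numbers 1 and 4 in its description, and the other libraries carry a single number. Of 24417 genes with a symbol, 19834 had a count in at least 1 library and 14164 were tested. Levels are CPM, counts scaled to a common library size, after TMM scaling, given as mean ± SD with n = 2 for Treg and n = 3 for reporter-null cells. Every log2 fold change is reporter-null minus Treg, with its standard error (SE), and every adjusted p comes from the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment unless another test is named.

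The comparison asked how transcripts of colonic cells with an active but Foxp3-deficient reporter allele differ from those of Foxp3-sufficient Treg cells. Foxp3 itself stood at 767 ± 3.97 CPM in Treg cells and 79.2 ± 3.06 CPM in reporter-null cells, a log2 fold change of -3.28 (SE 0.107, adjusted p = 5.45e-05). In single libraries it was 764 and 770.0 CPM in Treg replicates 1 and 2, and 75.7, 80.7 and 81.3 CPM in reporter-null replicates 1, 2 and 3. Thy1, of which the Thy1.1 reporter is an allele, was 18.8 and 21.4 CPM in the Treg libraries and 269.9, 269.3 and 300.5 CPM in the reporter-null libraries, a log2 fold change of 3.80 (SE 0.141, adjusted p = 8.48e-05). A count per symbol does not separate reporter Thy1.1 reads from reads of the endogenous gene. Both genes followed the group labels in all 5 libraries.

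**Figure D1:**
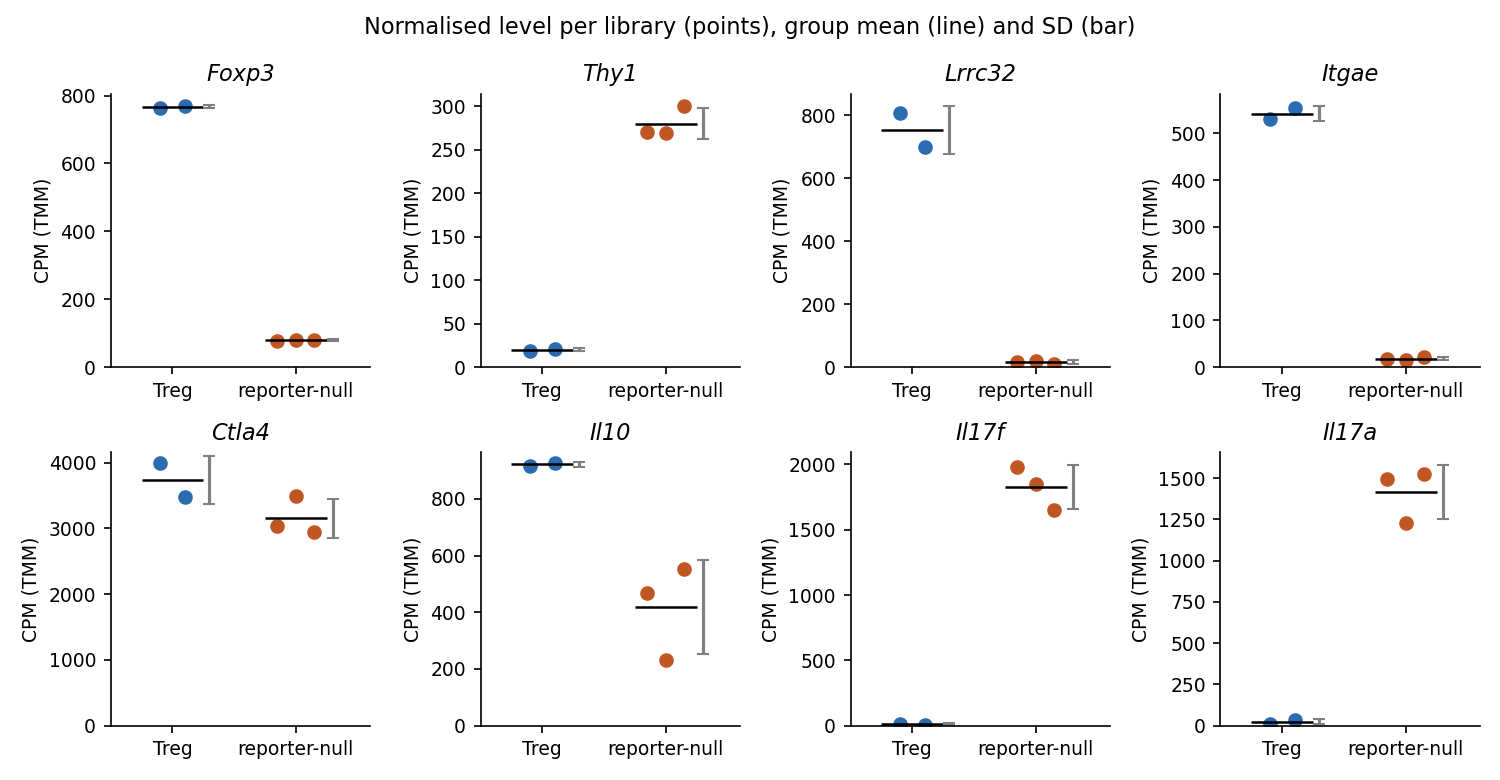
Levels in CPM after TMM scaling for 8 genes, with a point per library (2 Treg in blue, 3 reporter-null in orange), a line at the group mean and a grey bar for the SD. Foxp3, Lrrc32 and Itgae lie far lower and Thy1, Il17f and Il17a higher in all 3 reporter-null libraries, while Ctla4 overlaps between the groups and Il10 did not pass the test.

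Transcripts of Lrrc32, Itgb8 and Itgae, surface proteins of Treg cells, were among the strongest decreases in reporter-null cells, and those of the cytokine genes Il17f and Il17a among the strongest increases. Of the 14164 genes tested, 1245 (8.79%) changed at an adjusted p under 0.05, with 577 higher and 668 lower in reporter-null cells. Among them 344 rose and 390 fell by at least 2-fold, and 69 rose and 94 fell by at least 8-fold. In all 1245, every library of a group lay above every library of the other. Over all tested genes 5778 (40.8%) did so, where chance gives 20%. At an unadjusted p under 0.05 there were 3199 genes. The count depended on single libraries. It was 341 without Treg replicate 1, 405 without Treg replicate 2, 467 without reporter-null replicate 1, 2035 without reporter-null replicate 2 and 2152 without both Treg replicate 1 and reporter-null replicate 2.

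By the rule for named genes, the 8 largest increases were in Glp1r, Mstn, Il17f, C1ql1, Sprn, Il13, Tmeff2 and Il17a. Il17f, a cytokine of Th17 cells, stood at 10.1 ± 6.55 CPM in Treg and 1828 ± 168 CPM in reporter-null cells (log2 fold change 7.51, SE 0.550, adjusted p = 0.0022), and its log2 fold change was 8.39 without Treg replicate 1. Il17a rose from 24.3 ± 16.8 to 1417 ± 164 CPM (5.86, SE 0.592, adjusted p = 0.00762), with 6.84 without Treg replicate 2. Glp1r, the receptor for glucagon-like peptide, had a single count over both Treg libraries and 1064 over the reporter-null libraries, a depth-scaled ratio of 690 with a 95% counting interval of 124 to 27300. Without Treg replicate 2 the ratio was 317 (56.8 to 12500), and without Treg replicate 1, which held the count, Glp1r was at least 124-fold higher, with a limit of 3 counts over the Treg group. Such intervals and limits cover counting error only. Sprn (6.75, SE 0.300, adjusted p = 0.000159) and Tmeff2 (6.47, SE 0.489, adjusted p = 0.0015) were under 1 CPM in the Treg libraries, and Tmeff2 differed by 7.57 without Treg replicate 2. Mstn, which encodes myostatin, rose by 8.40 on the log2 scale (SE 0.939, adjusted p = 0.0126), and C1ql1 by 7.46 (SE 0.815, adjusted p = 0.00754). Each had 7 counts in the Treg group, all in Treg replicate 1 for Mstn and in Treg replicate 2 for C1ql1. With that library alone for the Treg group the log2 fold changes were 7.33 and 6.57, and with the other alone Mstn was at least 456-fold and C1ql1 at least 190-fold higher by the same limit. Without reporter-null replicate 1 neither passed, with an adjusted p of 0.0589 for Mstn and 0.0542 for C1ql1, limma-voom did not call Mstn (0.124), and over 14 alternatives the values ran from 1.48e-75 to 0.124 for Mstn and from 9.07e-54 to 0.0542 for C1ql1. Il13, a Th2 cytokine, was 6.73 higher (SE 1.305, adjusted p = 0.0471) and lost its call without Treg replicate 1 (0.229), Treg replicate 2 (0.232), reporter-null replicate 1 (0.12) or reporter-null replicate 3 (0.0549), within a range of 8.87e-43 to 0.507 over the 14 alternatives. It had 5 counts in the Treg group, and its log2 fold change was 5.998 without Treg replicate 2, while without Treg replicate 1 the ratio was 311 (55.7 to 12300).

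The 8 largest decreases were in Ccr3, Atp6v0d2, Lrrc32, Itgb8, Acod1, Itgae, Dnase1l3 and Phlpp1. Lrrc32 encodes GARP, which tethers latent TGF-beta to the Treg surface, and fell from 752 ± 76.2 to 15.2 ± 5.96 CPM (log2 fold change -5.63, SE 0.372, adjusted p = 0.00152). Itgb8, the integrin chain that helps release active TGF-beta, fell from 104.6 ± 13.7 to 2.22 ± 1.09 CPM (-5.54, SE 0.388, adjusted p = 0.00162). Itgae, which encodes CD103, the integrin chain that binds epithelial E-cadherin, fell from 542 ± 15.9 to 18.5 ± 3.09 CPM (-4.87, SE 0.166, adjusted p = 5.76e-05). Phlpp1, a phosphatase that removes activating phosphate from AKT, fell from 268 ± 2.35 to 11.8 ± 0.839 CPM (-4.50, SE 0.120, adjusted p = 2.61e-05). The chemokine receptor Ccr3 was lower by a log2 fold change of -6.78 (adjusted p = 0.00217), the proton pump subunit Atp6v0d2 by -5.94 (adjusted p = 0.000689) and Acod1, the enzyme that makes itaconate, by -5.03 (adjusted p = 0.00113). Dnase1l3 changed by -4.57 (SE 0.870, adjusted p = 0.0423), or -5.91 without reporter-null replicate 2, and lost its call without Treg replicate 1 (0.179), Treg replicate 2 (0.157), reporter-null replicate 1 (0.141) or reporter-null replicate 3 (0.0505), within a range of 7.31e-44 to 0.179 over 14 alternatives.

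**Figure D2:**
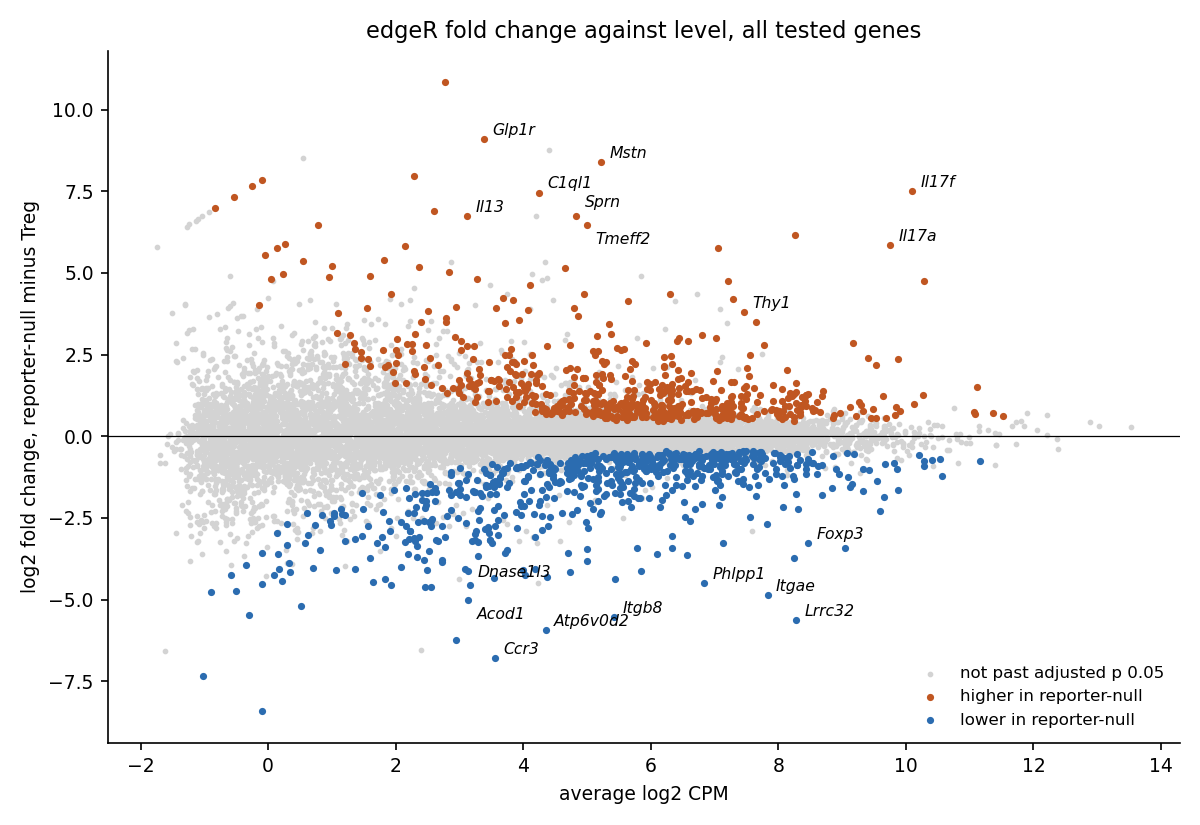
Log2 fold change (reporter-null minus Treg) against average log2 CPM for the 14164 tested genes, with the 577 higher genes in orange, the 668 lower genes in blue and the others in grey. Il17f and Il17a combine a high level with log2 fold changes of 7.51 and 5.86, and Lrrc32, Itgae and Phlpp1 lie at -5.63, -4.87 and -4.50.

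Genes of the Treg signature fell together. Of 28 tested, 17 were lower and 2 higher (19 lower and 2 higher when adjusted over the list alone), with a median log2 fold change of -1.53. Tnfrsf9, the co-stimulatory receptor 4-1BB, fell from 1154 ± 14.5 to 107 ± 0.697 CPM (-3.44, SE 0.108, adjusted p = 5.31e-05). The receptor Gpr83 (-3.62, adjusted p = 0.000207) and Swap70 (-3.42, adjusted p = 0.000159) fell too, as did Ikzf2, which encodes Helios (680 ± 13.0 to 50.8 ± 17.3 CPM, -3.74, SE 0.318, adjusted p = 0.00276) and Nrp1, which encodes neuropilin (170 ± 54.5 to 20.5 ± 6.43 CPM, -3.06, SE 0.316, adjusted p = 0.00504). Tnfrsf18, which encodes GITR, fell as well (931 ± 68.7 to 316 ± 10.8 CPM, -1.56, SE 0.112, adjusted p = 0.000763). Il2ra, the high-affinity IL-2 receptor chain, fell from 433 ± 14.9 to 235 ± 23.0 CPM (-0.88, SE 0.122, adjusted p = 0.00711), a call lost without Treg replicate 1 (0.0685) or Treg replicate 2 (0.0784), within a range of 4.05e-11 to 0.0784 over 14 alternatives. Ctla4, the inhibitory receptor that competes with CD28, stood at 3734 ± 368 CPM in Treg and 3154 ± 292 CPM in reporter-null cells (-0.24, SE 0.153, adjusted p = 0.418). Socs2, an inhibitor of cytokine signalling, was higher (1.44, adjusted p = 0.00162). The list passed the camera set test (adjusted p = 3.1e-33) and was the only list of the 37 tested to pass with an estimated correlation (adjusted p = 0.0298).

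**Figure D3:**
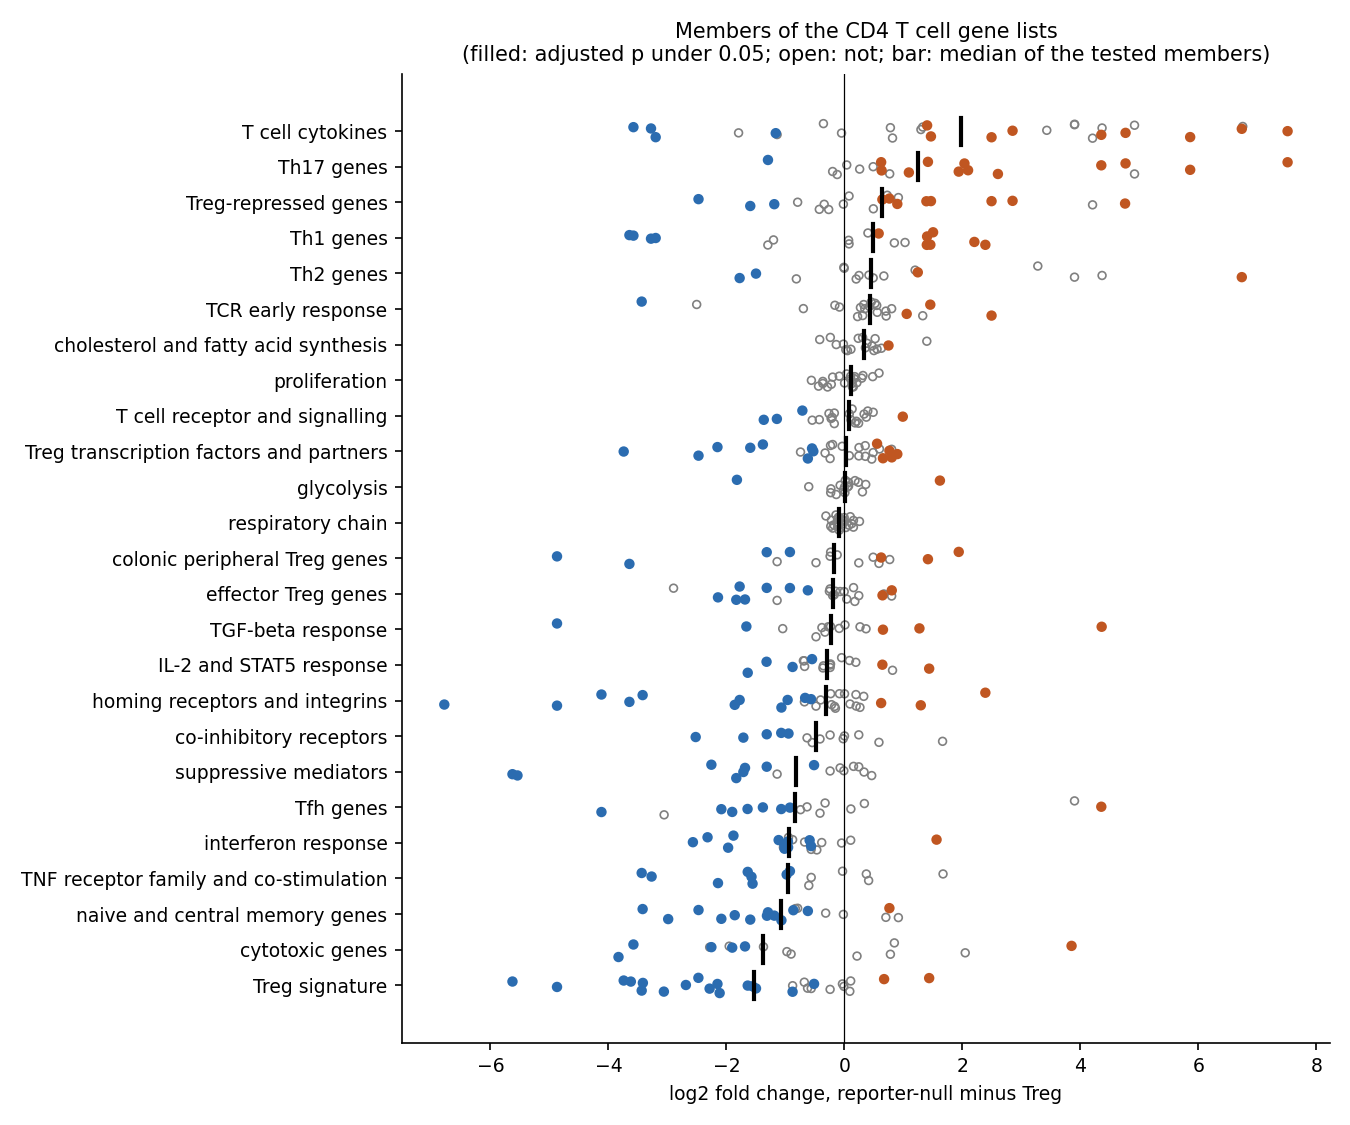
Log2 fold change (reporter-null minus Treg) of each tested member of the 25 CD4 T cell gene lists, a row per list, with members past an adjusted p of 0.05 filled (orange higher, blue lower), the others open, and a bar at the list's median. The median ran from -1.53 for the Treg signature to 1.98 for T cell cytokines.

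Genes that Treg cells normally hold down were higher in part. Of 21 tested, 8 were higher and 3 lower (9 higher and 3 lower when adjusted over the list alone). Pde3b, a phosphodiesterase that breaks down cyclic AMP and is repressed by Foxp3, rose from 8.89 ± 1.86 to 240 ± 17.7 CPM (4.76, SE 0.189, adjusted p = 0.000112). Cd40lg, the ligand that activates CD40 on antigen-presenting cells, rose by 2.49 on the log2 scale (SE 0.161, adjusted p = 0.000606), and Tnfsf8, which encodes CD30 ligand, by 2.85 (SE 0.191, adjusted p = 0.000626). Il7r, another member, differed by -0.02 and was not called. The set test gave an adjusted p of 9.93e-05, and with an estimated correlation adjusted p = 0.0724.

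Cytokine and chemokine genes were more often higher than lower in reporter-null cells. Of 28 tested, 9 were higher and 4 lower (15 higher and 6 lower when adjusted over the list alone), with a median of 1.98. Il17a, Il17f, Cd40lg and Tnfsf8 were among the higher genes, as was Ifng, the Th1 cytokine, which rose from 32.0 ± 10.9 to 84.6 ± 6.19 CPM (1.40, SE 0.219, adjusted p = 0.0116). Ltb, which encodes lymphotoxin beta, fell from 738 ± 4.97 to 329 ± 35.4 CPM (-1.16, SE 0.127, adjusted p = 0.00298). Il10, the main anti-inflammatory cytokine of colonic Treg cells, stood at 922 ± 8.72 CPM in Treg and 418 ± 166 CPM in reporter-null cells (-1.14, SE 0.366, adjusted p = 0.146). Its lowest library was reporter-null replicate 2 at 232 CPM, and without that library the adjusted p was 0.00215, within a range of 0.000909 to 0.433 over 14 alternatives. Il2 (4.21, SE 1.08, adjusted p = 0.0728) passed without the same library (0.00116, range 3.37e-12 to 0.346). Its log2 fold change was 3.52 without Treg replicate 1 and 3.41 without reporter-null replicate 3, and without Treg replicate 2, with 2 Treg counts left, the ratio was 55.6 (95% counting interval 15.3 to 461). DESeq2 called Il10 (0.00412), Il2 (0.000144) and Il4 (0.00148). Il4 differed by 3.90 (SE 1.183, adjusted p = 0.176), with 14.5 ± 11.1 CPM in Treg and 217 ± 156 CPM in reporter-null cells. It passed without both Treg replicate 1 and reporter-null replicate 2 (log2 fold change 3.72), a fit that leaves 1 Treg library. The log2 fold change of Il4 was 3.28 without Treg replicate 1, 5.04 without Treg replicate 2 and 3.25 without reporter-null replicate 3. Tgfb1 differed by 0.33 (SE 0.134, adjusted p = 0.202), at 231 ± 25.5 and 290 ± 26.6 CPM. The set test called the list higher (adjusted p = 1.22e-08), and with an estimated correlation adjusted p = 0.254.

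Genes of the Th17 list rose, with 12 of 20 tested genes higher and 1 lower (14 higher and 1 lower when adjusted over the list alone). The membrane proteins Tmem176b (2.03, SE 0.134, adjusted p = 0.000626) and Tmem176a (2.10, SE 0.165, adjusted p = 0.000991) rose with Il17a and Il17f. Maf, a further regulator on the list, differed by 0.49 (SE 0.238, adjusted p = 0.301), at 117 ± 6.06 and 164 ± 48.1 CPM, and passed without reporter-null replicate 2 (0.0404, range 0.0151 to 0.598). The set test gave an adjusted p of 5.54e-17, and with an estimated correlation adjusted p = 0.0611. Of 4 tested genes from a list of gamma-delta T cell markers, 2 were higher as well and none lower (3 higher when adjusted over the list alone). They were 5830411N06Rik (7.03 ± 0.196 to 506 ± 109 CPM, 6.17, adjusted p = 0.000141) and the kinase gene Blk (2.88 ± 1.23 to 44.0 ± 9.17 CPM, 3.92, adjusted p = 0.00152), and that list passed with an adjusted p of 2.78e-08, and with an estimated correlation adjusted p = 0.0724.

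Th1 genes split. Of 18 tested, 7 were higher and 4 lower (9 higher and 4 lower when adjusted over the list alone), with a median of 0.49 and a mean of -0.16. The chemokine receptor Cxcr6 rose from 191 ± 15.5 to 1002 ± 88.2 CPM (2.39, SE 0.144, adjusted p = 0.000485), and the IL-18 receptor chains Il18rap (1.40, adjusted p = 0.00152) and Il18r1 (1.46, adjusted p = 0.00342) rose with it. Cxcr3, the chemokine receptor of Th1 cells and of Treg cells that control them, fell from 212 ± 3.98 to 17.0 ± 6.02 CPM (-3.64, SE 0.321, adjusted p = 0.00313). Tbx21, which encodes the Th1 regulator T-bet, differed by 0.07 (SE 0.183, adjusted p = 0.871), at 54.4 ± 0.867 and 57.1 ± 11.4 CPM. The set test called the list higher (adjusted p = 0.00894), and with an estimated correlation adjusted p = 0.357. That call was lost without Treg replicate 1 (0.0613), without Treg replicate 2 (0.0512) and without both Treg replicate 1 and reporter-null replicate 2 (0.996), within a range of 0.00237 to 0.996.

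Among 16 Th2 genes, 2 were higher and 2 lower (3 higher and 2 lower when adjusted over the list alone). Gata3, which encodes the Th2 regulator, differed by 0.25 (SE 0.332, adjusted p = 0.742), at 373 ± 50.7 and 442 ± 153 CPM, and passed without reporter-null replicate 2 (0.0399, range 0.0399 to 0.940). The called members were Il13, Dusp6, Ecm1 and Ccr8, of which Dusp6, a MAP kinase phosphatase, rose by 1.24 (adjusted p = 0.00682) and lost its call without Treg replicate 1 (0.0767, range 1.08e-10 to 0.0767). Ecm1 fell by 1.5 on the log2 scale (adjusted p = 0.00416) and lost its call without Treg replicate 2 (0.0533, range 1.37e-12 to 0.0533). Ccr8 fell by 1.78 (adjusted p = 0.0191) and lost its call without Treg replicate 1 (0.0654), Treg replicate 2 (0.114), reporter-null replicate 1 (0.0578) or reporter-null replicate 3 (0.0599), within a range of 3.37e-15 to 0.114. The set test did not call the list (adjusted p = 0.204), but did without reporter-null replicate 2 (0.00252) and without both that library and Treg replicate 1 (2.57e-05), within a range of 2.57e-05 to 0.313.

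Receptors of the TNF family and co-stimulatory receptors fell, with 8 of 14 tested lower and none higher (8 lower and 1 higher when adjusted over the list alone). Besides Tnfrsf9 and Tnfrsf18, Tnfrsf4, which encodes OX40, fell from 1589 ± 190 to 510 ± 36.0 CPM (-1.64, SE 0.134, adjusted p = 0.0011), and Cd27 fell from 302 ± 84.8 to 31.4 ± 3.11 CPM (-3.27, SE 0.194, adjusted p = 0.000485). The set test gave an adjusted p of 2.2e-13, and with an estimated correlation adjusted p = 0.0611. Of 16 suppressive mediators, 8 were lower and none higher (9 lower when adjusted over the list alone), led by Lrrc32 and Itgb8 (adjusted p = 1.92e-08, and with an estimated correlation adjusted p = 0.0611). Of 14 co-inhibitory receptors and ligands, 5 were lower and none higher (6 lower when adjusted over the list alone). Tigit, an inhibitory receptor that stood on both lists, fell from 363 ± 12.5 to 146 ± 22.4 CPM (-1.32, SE 0.145, adjusted p = 0.00308). The co-inhibitory list gave an adjusted p of 0.000345, and with an estimated correlation adjusted p = 0.0879.

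Of 24 effector Treg genes, 7 were lower and 2 higher, and the counts were the same when adjusted over the list alone. Tigit was among the lower genes, as was the granzyme gene Gzmb (1095 ± 157 to 341 ± 72.6 CPM, -1.68, SE 0.202, adjusted p = 0.00429), whose call was lost without Treg replicate 2 (0.0522, range 7.69e-17 to 0.0522). The list's adjusted p was 0.00114, and with an estimated correlation adjusted p = 0.21, and the call was lost without Treg replicate 2 (0.0702, range 2.83e-05 to 0.0702). Of 15 cytotoxic genes, 5 were lower and 1 higher (9 lower and 4 higher when adjusted over the list alone). The granzyme gene Gzma fell from 72.4 ± 15.3 to 5.09 ± 1.32 CPM (-3.83, SE 0.257, adjusted p = 0.000653) and the protease gene Ctsw from 99.1 ± 12.7 to 26.5 ± 3.13 CPM (-1.90, SE 0.148, adjusted p = 0.000967). The cytotoxic list gave an adjusted p of 0.000969, and with an estimated correlation adjusted p = 0.152. Beside it, CD8 T cell markers had 1 of 7 tested genes lower and none higher (4 lower and 1 higher when adjusted over the list alone, list adjusted p = 0.0218, and with an estimated correlation adjusted p = 0.224). The called gene was Cd7 (-4.34, adjusted p = 0.00818), which is also on the list of natural killer and innate lymphoid markers. Cd8b1 was not called (-1.08, adjusted p = 0.118). Of the 7 tested genes, 6 are on another list as well. The call of the CD8 list was lost without Treg replicate 1 (0.166, range 0.00942 to 0.166).

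Genes of naive and central memory T cells, which recirculate through lymph nodes, were lower in reporter-null cells in 12 of 19 cases and higher in 1 (12 lower and 2 higher when adjusted over the list alone). Il6st, the shared signalling chain of the IL-6 receptor family, fell from 206 ± 1.17 to 48.4 ± 7.51 CPM (-2.09, SE 0.146, adjusted p = 0.000706), Il6ra by a log2 fold change of -1.30 (adjusted p = 0.00277) and Klf3 by -1.31 (adjusted p = 0.000991). The set test gave an adjusted p of 1.12e-13, and with an estimated correlation adjusted p = 0.0611. Of 28 homing receptors and integrins, 11 were lower and 3 higher (12 lower and 3 higher when adjusted over the list alone). Itgae, Ccr3 and Cxcr3 were lower, and Cxcr6 and Ccr1 (1.29, SE 0.116, adjusted p = 0.0015) were higher. That list gave an adjusted p of 7.49e-07, and with an estimated correlation adjusted p = 0.0611. Of 16 genes of follicular helper T cells, 7 were lower and 1 higher, also when adjusted over the list alone. Cxcr5, the receptor that guides cells into B cell follicles, fell from 132 ± 30.6 to 7.56 ± 2.95 CPM (-4.12, SE 0.351, adjusted p = 0.00297), and Sh2d1a, the adaptor SAP, by -1.90 (adjusted p = 0.000626). The follicular helper list gave an adjusted p of 2.47e-07, and with an estimated correlation adjusted p = 0.0714.

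Interferon-induced genes were lower in 11 of 21 cases and higher in 1 (16 lower and 1 higher when adjusted over the list alone). Usp18, a brake on interferon signalling, fell from 24.0 ± 6.57 to 4.04 ± 0.470 CPM (-2.57, SE 0.245, adjusted p = 0.00183). Ifit1 fell from 30.7 ± 4.36 to 7.82 ± 0.976 CPM (-1.97, SE 0.188, adjusted p = 0.00182) and Oas1a from 39.7 ± 6.31 to 10.8 ± 0.738 CPM (-1.88, SE 0.167, adjusted p = 0.00147). The set test gave an adjusted p of 1.12e-10, and with an estimated correlation adjusted p = 0.0714. Of 18 IL-2 and STAT5 response genes, 4 were lower and 2 higher (7 lower and 2 higher when adjusted over the list alone). The cytokine signalling inhibitors in it went both ways, since Socs3 had a log2 fold change of -1.32 (adjusted p = 0.00152) and Socs2 rose by 1.44. The list's adjusted p was 0.00577, and with an estimated correlation adjusted p = 0.244, and it lost its call without Treg replicate 2 (0.0849, range 0.000815 to 0.0849).

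Treg transcription factors and partners went both ways, with 8 of 28 lower and 5 higher (8 lower and 6 higher when adjusted over the list alone). Ikzf4, which encodes the Helios relative Eos, fell from 96.3 ± 9.86 to 21.7 ± 1.1 CPM (-2.15, SE 0.122, adjusted p = 0.000407). Lef1, a transcription factor of naive T cells, was lower too (181 ± 13.9 to 32.7 ± 11.4 CPM, -2.47, SE 0.294, adjusted p = 0.00726), a call lost without Treg replicate 1 (0.0776) or Treg replicate 2 (0.0644), within a range of 1.04e-37 to 0.0776. The set test did not call the list (adjusted p = 0.254), but did without reporter-null replicate 2 (0.0192, range 0.00435 to 0.991). Of 16 genes of colonic peripheral Treg cells, 4 were lower and 3 higher (5 lower and 4 higher when adjusted over the list alone). Itgae, Tigit and Cxcr3 fell, and the set test gave an adjusted p of 0.0596, with calls without a filter on low counts (0.0242), without reporter-null replicate 1 (0.0341) or 2 (0.0356) and without both Treg replicate 1 and reporter-null replicate 2 (0.0121), and a range of 0.0121 to 0.300. Of 15 genes of the TGF-beta response, 3 were higher and 2 lower (3 higher and 3 lower when adjusted over the list alone, list adjusted p = 0.287). Its receptor chains Tgfbr2 (187 ± 0.0822 to 452 ± 49.1 CPM, 1.27, SE 0.134, adjusted p = 0.00268) and Tgfbr3 (2.42 ± 1.35 to 50.2 ± 7.60 CPM, 4.36, SE 0.393, adjusted p = 0.0024, and 5.10 without Treg replicate 2) rose, and Cd101 fell with Itgae (-1.66, adjusted p = 0.00123). Without both Treg replicate 1 and reporter-null replicate 2 that list was called lower (0.0325, range 0.0325 to 0.929).

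Genes of the T cell receptor and its signalling chain were not called as a set (adjusted p = 0.451), with 1 of 21 higher and 3 lower (3 higher and 4 lower when adjusted over the list alone). Cd2 (1174 ± 138 to 455 ± 32.7 CPM, -1.37, SE 0.131, adjusted p = 0.00186) and Dgka (-1.15, SE 0.102, adjusted p = 0.0015) fell. Cd4 rose from 701 ± 26.4 to 1391 ± 147 CPM (0.99, SE 0.141, adjusted p = 0.00796), a call lost without Treg replicate 1 (0.11) or Treg replicate 2 (0.0827), within a range of 8.09e-13 to 0.11. None of 22 proliferation genes was called by the edgeR test, over all genes or over the list alone (list adjusted p = 0.824), while 3 had an unadjusted p under 0.05, and DESeq2 called 1, limma-voom 0 and voom with quality weights 1. None of 27 respiratory chain genes was called by edgeR, DESeq2 or either form of limma-voom, and 0 had an unadjusted p under 0.05 (list adjusted p = 0.566). Of 18 glycolysis genes, Hk2 was higher and Slc16a3 lower, also over the list alone (list adjusted p = 0.895), and each lost its call without Treg replicate 1 (0.213 for Hk2, 0.146 for Slc16a3) or Treg replicate 2 (0.104 and 0.134), and Hk2 also without reporter-null replicate 1 (0.136). Their ranges were 0.000282 to 0.213 for Hk2 and 5.52e-15 to 0.146 for Slc16a3. Early T cell receptor response genes were higher in 3 of 22 cases and lower in 1 (4 higher and 2 lower when adjusted over the list alone, list adjusted p = 0.0394, and with an estimated correlation adjusted p = 0.569). That call was lost without Treg replicate 1 (0.243), reporter-null replicate 1 (0.109) or reporter-null replicate 2 (0.0571), within a range of 0.000185 to 0.243. The list shares 6 tested genes, Fosb among them, with the list for dissociation and heat shock, which was also called higher (adjusted p = 0.00375) and also lost its call without Treg replicate 1 (0.862), with 1e-09 without Treg replicate 2. Of 18 cholesterol and fatty acid synthesis genes, 1 was higher and none lower, and none passed when adjusted over the list alone (list adjusted p = 0.0394, and with an estimated correlation adjusted p = 0.549). Its call was lost without Treg replicate 1 (0.17), reporter-null replicate 1 (0.0961) or reporter-null replicate 2 (0.131), within a range of 0.00663 to 0.451.

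Treg replicate 1 and reporter-null replicate 2 stood apart from the other libraries. On the leading principal component, with 48% of the variance, they lay at -55.2 and -80.3, against 25.8 for Treg replicate 2 and 51.3 and 58.3 for reporter-null replicates 1 and 3. The next component, with 36.9%, separated Treg from reporter-null cells. The summed level of 16 epithelial markers was 422 CPM in Treg replicate 1 and 2074 CPM in reporter-null replicate 2, against 52.8, 41.2 and 44.4 CPM in Treg replicate 2 and reporter-null replicates 1 and 3. The heat shock genes Hspa1a and Hspa1b took 0.396% and 0.568% of the counts in those libraries, against 3.09%, 3.19% and 2.67% in the others. As a set between the groups, epithelial markers had no called member by edgeR or limma-voom and 0 with an unadjusted p under 0.05 (list adjusted p = 0.724). DESeq2 called none either, but gave no adjusted p for Epcam, Krt8 and Krt19, so it did not test them. Without reporter-null replicate 2 the list was called lower (0.0271, range 0.0271 to 0.747). Of 22 dissociation and heat shock genes, 3 were higher and none lower (6 higher when adjusted over the list alone, list adjusted p = 0.00375, and with an estimated correlation adjusted p = 0.631). That call was lost without Treg replicate 1 (0.862) and without both libraries (0.649), within a range of 1e-09 to 0.862. Of 28 ribosomal protein genes none was called by these tools and 0 had an unadjusted p under 0.05 (list adjusted p = 0.125), but the list was called lower without Treg replicate 2 (0.00721) or reporter-null replicate 3 (0.000172), within a range of 0.000172 to 0.970. None of the mitochondrially encoded genes written in the list were tested.

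**Figure D4:**
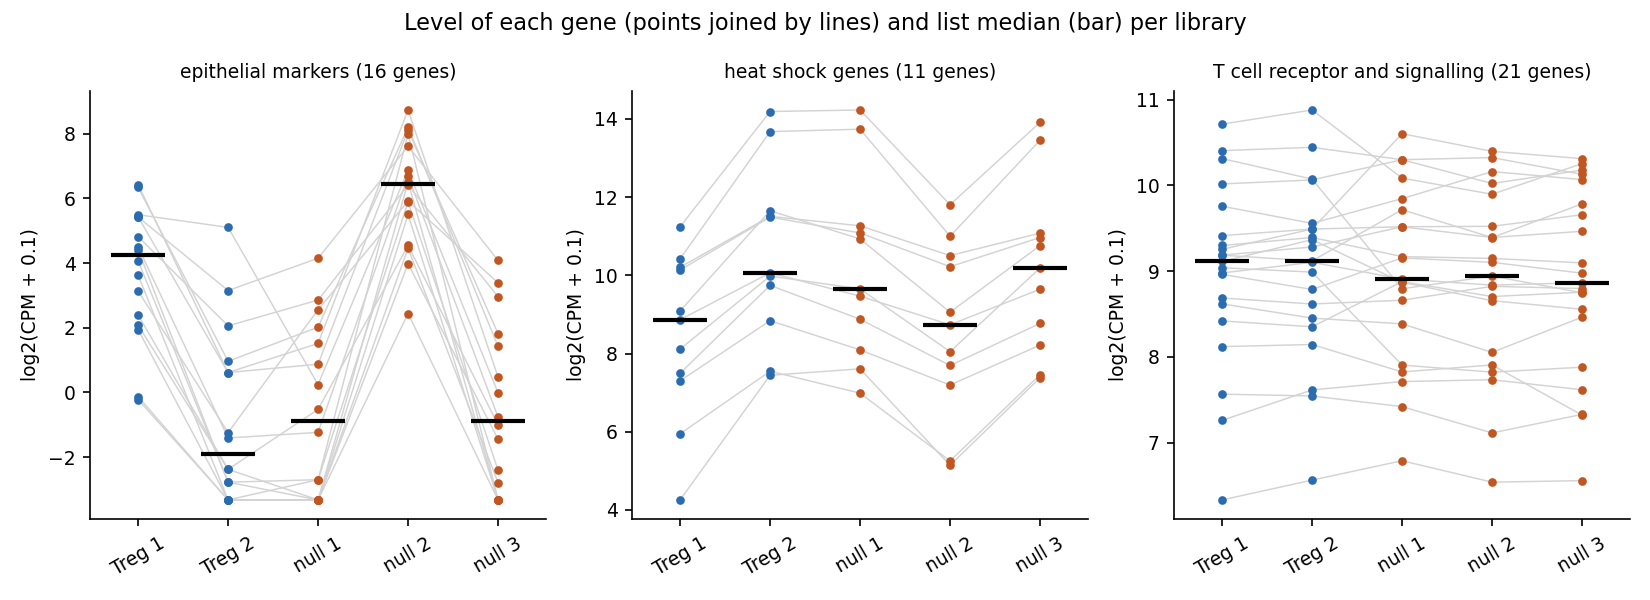
Log2(CPM + 0.1) of 16 epithelial markers, 11 heat shock genes and 21 T cell receptor and signalling genes in each of the 5 libraries, with a line per gene and a bar at the median. Epithelial markers are higher and heat shock genes lower in Treg replicate 1 and reporter-null replicate 2, whose median log2 ratios to the rest of their group were 4.80 and 6.77 for epithelial markers, -1.87 and -1.79 for heat shock genes and -0.04 and -0.06 for T cell receptor and signalling genes.

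In 7 further lists, of markers of other cell types, 0 to 2 markers per list were called. Among 10 B and plasma cell markers 1 was lower, Cd79b (19.8 ± 0.828 to 7.11 ± 0.306 CPM, -1.48, adjusted p = 0.0046), which lost its call without Treg replicate 1 (0.0588, range 1.42e-10 to 0.0588). The list was not called (adjusted p = 0.307), but was called lower without Treg replicate 2 (0.0119) or reporter-null replicate 2 (0.0358), within a range of 0.0119 to 0.53. Among 13 macrophage and monocyte markers 1 was lower, Cybb (-2.25, adjusted p = 0.0256), whose call was lost without Treg replicate 1 (0.156), Treg replicate 2 (0.134) or reporter-null replicate 1 (0.111), within a range of 1.45e-17 to 0.156, and the list's adjusted p was 0.869. Among 7 dendritic cell markers 1 was higher (list adjusted p = 0.718). It was Clec10a, which had no count in the Treg libraries and 60 in the reporter-null libraries, at least 13-fold higher with a limit of 3 counts over the Treg group, and its adjusted p of 0.0275 became 0.122, 0.107, 0.122 and 0.0593 without Treg replicates 1 and 2 and reporter-null replicates 1 and 3, within a range of 0.00118 to 0.122. Among 9 natural killer and innate lymphoid markers, Kit was higher and Cd7 lower (list adjusted p = 0.623). Cd7 lost its call without Treg replicate 1 (0.0645) or Treg replicate 2 (0.0537), within a range of 1.22e-33 to 0.0645, and Kit without Treg replicate 1 (0.31), Treg replicate 2 (0.225) or reporter-null replicate 1 (0.138), within 6.46e-06 to 0.31. Of the granulocyte and mast cell markers only 2 reached the tested level, Cpa3 and Ccr3, and the lower level of Ccr3 gave a list adjusted p of 0.00215, and with an estimated correlation adjusted p = 0.21. That call was lost without Treg replicate 1 (0.191), Treg replicate 2 (0.0651) or a filter on low counts (0.706), within a range of 8.27e-05 to 0.706. Among 9 stromal and endothelial markers 1 was higher, Pdgfrb (0.220 ± 0.0810 to 8.28 ± 2.07 CPM, 5.18, adjusted p = 0.00181), and the list was not called (adjusted p = 0.525). None of 3 erythroid markers was called by edgeR, DESeq2 or limma-voom, and 0 had an unadjusted p under 0.05 (list adjusted p = 0.963). A missing call does not show that such RNA was absent, since some uncalled markers peaked in reporter-null replicate 2. In reporter-null replicates 1, 2 and 3, Dcn was 0.0542, 27.1 and 0.0445 CPM and Hba-a1 1.14, 14.1 and 0.49 CPM. Cd74 was 88.3, 383.6 and 90.1 CPM there. Cd68 (1.35, 2.78 and 3.1 CPM) did not peak in that library. In each of these 7 lists of other cell types, the counts were the same when adjusted over the list alone. In the lists for T cell receptor signalling, glycolysis, Treg transcription factors, macrophages and erythroid cells, none of them called, the median was above 0 while the set test pointed to lower, and in the dendritic cell list the median was below 0 while the test pointed to higher.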

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

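Leaving out both Treg replicate 1 and reporter-null replicate 2 was chosen after the data were seen, and the other alternatives were planned. Against 1245 changed genes (577 higher, 668 lower), RLE factors, upper quartile factors, limma-voom, no filter, a CPM filter and thinned counts gave 1221 to 1339. DESeq2 called 2321 (1208 higher, 1113 lower) of 19762 genes, without the filter that left 14164 for edgeR, so the counts are over unlike sets of genes. Voom with quality weights called 2222 (1029 higher, 1193 lower). The cause of these higher counts was not tested. DESeq2 also made more false calls in the simulation. That simulation drew genes independently and only those past the edgeR filter, so it cannot explain the count of DESeq2 here. Leaving out a replicate gave 341 to 2035 genes (146 to 926 higher, 192 to 1109 lower), in which fits with fewer samples can lose calls, and the cause of the rise was not tested. Without both libraries that stand apart there were 2152 genes (944 higher, 1208 lower), 1106 of them among the 1245. A stricter adjusted p under 0.01 left 489 (208 higher, 281 lower), and a fold of at least 2 left 734 (344 higher, 390 lower), both by construction. All genes shared with the 1245 kept their direction in each alternative. Of 145 named genes 92 changed, and 60 of these kept their call in all 5 leave-one-out fits. Of the 37 lists 21 passed by camera, which compares a list with the other genes, and 1 did with an estimated correlation and 15 to 24 with a replicate left out. The rotation test fry has another null, no change of the list on balance. It called 18, without the lists for Th1 (adjusted p = 0.0506), the early T cell receptor response (0.333), cholesterol and fatty acid synthesis (0.158) and dissociation and heat shock (0.332), and with that for colonic peripheral Treg cells (0.0121). The epithelial list turned from higher, not called, to lower without reporter-null replicate 2 (adjusted p = 0.0271, within 0.0271 to 0.424 over the left-out replicates), the library that holds most of its transcripts. Its member Epcam, at a log2 fold change of 0.01 and not called, was -5.34 to 0.59 with a replicate left out. It was called lower without reporter-null replicate 2 (-5.34), and was -5.12 without both libraries that stand apart. Without Treg replicate 1, Krt8 and Krt19 rose to 6.63 and 5.75, so Epcam differed far less between the Treg libraries than they did. The replicate numbers pair only 2 libraries per group, and no label says what a number marks. The headers of the count columns carry the numbers of the descriptions. With a replicate block by title number 24 genes passed (12 higher, 12 lower), and by description number 1399. Either block leaves few residual degrees of freedom for 5 libraries, so the drop to 24 genes is no measure of how firm the calls are. The block by title number added a call for ribosomal proteins (lower, adjusted p = 1.03e-07). That by description number called the epithelial list higher (3.31e-10), opposite to the call without reporter-null replicate 2, and also the lists for Th2 (0.00411) and colonic peripheral Treg cells (0.00737), but not those for Th1 (0.0562) and cholesterol and fatty acid synthesis (0.174). Deviations from the group means correlated across genes at -0.511 and -0.602 for the same title number, and at 0.602 and 0.481 for the same description number. With 2 Treg libraries these deviations are mirror images, so -0.602 and 0.602 are the same value, and the 4 values are no separate evidence for a numbering. At this depth, genes with few counts in a group, such as Glp1r and Clec10a, have folds that are bounded only by counting error.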

Other observations

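The genes of the opening paragraphs, and the tests of the explanations that follow them, were chosen after the results were seen. Several signalling and regulatory genes differed strongly between the groups with a small spread. Prr5l, which encodes a partner of mTOR complex 2, rose from 4.03 ± 0.139 CPM (SD, n = 2) to 217 ± 8.46 CPM (SD, n = 3), a log2 fold change of 5.75 (SE 0.142, edgeR adjusted p = 2.61e-05). Of the phosphodiesterases, Pde3b was higher by 4.76 on the log2 scale, while Pde2a fell from 196 ± 16.7 to 32.2 ± 6.53 CPM (-2.61, SE 0.183, edgeR adjusted p = 0.000706). Vdr, the vitamin D receptor, rose from 13.7 ± 2.12 to 252 ± 21.3 CPM (4.20, SE 0.170, edgeR adjusted p = 0.000112), and Hlf, a transcription factor of the PAR bZIP family, from 24.7 ± 0.358 to 200.2 ± 20.1 CPM (3.02, SE 0.142, edgeR adjusted p = 0.000178). These genes kept their calls in each leave-one-out fit.

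Of the apolipoprotein L genes, Apol7b rose from 17.3 ± 2.10 to 129.9 ± 6.28 CPM (2.90, SE 0.139, edgeR adjusted p = 0.000187) and Apol7e from 20.1 ± 0.862 to 172 ± 17.2 CPM (3.10, SE 0.143, edgeR adjusted p = 0.000178), while Apol9b fell from 29.5 ± 4.35 to 2.65 ± 0.981 CPM (-3.48, SE 0.322, edgeR adjusted p = 0.00162). Members of this family are close copies, so the value of a single member is uncertain where reads match several of them. Among cytokine genes, Csf2 was 34.2, 4.18 and 52.7 CPM in reporter-null replicates 1, 2 and 3, Il22 was 84.3, 36.4 and 161 CPM and Il5 was 23.1, 6.58 and 35.1 CPM, with reporter-null replicate 2 lowest each time. They were not called by edgeR (adjusted p = 0.107, 0.152 and 0.232), DESeq2 called all 3 (adjusted p = 9.4e-07, 0.00106 and 0.0309), Csf2 passed without reporter-null replicate 2 (3.52e-07), and all 3 passed without both Treg replicate 1 and reporter-null replicate 2 (6.41e-67, 3.46e-43 and 4.39e-31). Over 14 alternatives the ranges were 6.41e-67 to 0.664 for Csf2, 3.46e-43 to 0.371 for Il22 and 4.39e-31 to 0.466 for Il5.

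Treg replicate 1 and reporter-null replicate 2 stood apart from the other libraries by epithelial and heat shock transcripts. The difference was not limited to these, since some stromal, erythroid and antigen-presenting cell markers (Dcn, Hba-a1 and Cd74) were also highest of their group in reporter-null replicate 2. All 16 tested epithelial markers, none of them on another list and 6 at 1 CPM or more in both Treg libraries, lay above every other library of the own group in both groups, with Krt8 at 86.1 and 426 CPM and Krt19 at 81.0 and 294 CPM in cells selected on GFP or Thy1.1. RNA of epithelial cells as their source stays open, because the pattern was seen in these same markers and their count does not test it. Dilution by RNA of other cells does not account for the lower heat shock transcripts, because T cell receptor and signalling genes kept their level (median log2 ratio to the rest of the group -0.06 in the lower case) while 11 heat shock genes had a median of -1.79 or lower. Both libraries carry the number 2 in their descriptions. The deviations of same-numbered libraries correlated across genes at 0.481 in the lower case, but with 2 Treg libraries the deviations of one mirror those of the other, so this restates that the 2 libraries stand apart and lends no separate support to a shared animal, day or handling. No label says what the number marks, so such a difference cannot be told apart from others between these libraries. No biological explanation was tested.

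Genes associated with IL-17-producing gamma-delta T cells (5830411N06Rik and Blk) were higher in reporter-null libraries together with Il17a and Il17f. Gamma-delta T cells as most of the reporter-null cells is an explanation the data argue against, since Cd4 was higher there, with a log2 fold change of 0.989 (a call lost without Treg replicate 1, 0.11, or Treg replicate 2, 0.0827), and lay above both Treg libraries in every reporter-null library. A minor share of such cells stays open. Of the 4 tested markers 2 were called higher, and none of the 4 is on another list. Cd163l1 was higher but not called (2.64, edgeR adjusted p = 0.0525). Sox13 did not follow the called markers (0.53, edgeR adjusted p = 0.912). It was 1.79 and 0.139 CPM in Treg replicates 1 and 2, and 0.0542, 3.94 and 0.178 CPM in reporter-null replicates 1, 2 and 3. At such low levels Sox13 does not decide the question. Of 10 markers written, only these 4 were among the deposited genes. T cell receptor constant genes were not found under the symbols looked up, so such cells could not be tested directly. A Foxp3-dependent difference within CD4 T cells, which the design names, stays open as well and was not tested apart.

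Ccdc22, the neighbour of Foxp3, was lower in reporter-null cells (144 ± 1.31 to 63.4 ± 8.91 CPM, -1.18, SE 0.139, edgeR adjusted p = 0.00415), a call lost without Treg replicate 1 (0.0507, range 3.89e-11 to 0.0507 over 14 alternatives). An effect of that size shared by the region is argued against, since the 19 other genes among the 20 nearest tested ones had a median log2 fold change of 0.147 (SD 0.568). None of them was called lower, and Syp and Pim2 were called higher, with calls lost without Treg replicate 1 (0.143 and 0.272), Treg replicate 2 (0.12 and 0.107) or reporter-null replicate 1 (0.0532 and 0.149), within ranges of 1.14e-05 to 0.143 and 0.00107 to 0.272. A smaller or more local effect stays open. Foxp3 reads counted for Ccdc22 stay open as a source of the loss, since the counting of overlapping reads is not given in the sources used here. The loss of Ccdc22 was 80.3 CPM against 688 CPM for Foxp3, or 11.7%. This comparison cannot test it, because Ccdc22, at 144 CPM in Treg cells, could not have lost more than Foxp3 did. An effect of the reporter-null allele on its neighbour stays open too.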
